A study of Asparagus officinalis with 15 samples.

How the data were processed

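Small RNAs of garden asparagus (Asparagus officinalis) were measured in 15 libraries: 8 from the tips of 6 inch spears, 4 from flower buds, and 1 each from leaf, root and shoot. The labels name 3 genotypes in spear tips, female, male and supermale, and the series describes them as XX, XY and YY. Female and male spear tips came from lines 10, 8A and 8B, and supermale tips from lines 8A and 8B. Buds were labelled female or male and early or mid, with 1 library for each combination. The genotype of the leaf, root and shoot plants was not given in the sources used here.

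The deposited values were raw counts of each distinct sequence, or tag, and were not normalized. Per the labels' protocols, the authors extracted total RNA with TRIzol, prepared small RNA libraries with an Illumina small RNA kit, trimmed the adapters and counted how often each distinct small RNA was read. The trimming tool, its settings and any filter were not given in the sources used here. Tags were 18 to 46 nt long in all 15 libraries. Totals ran from 29122841 counts in root to 59076580 in the mid female bud, and 68.5% to 75.9% of the distinct tags of a library were seen once. The labels do not say whether libraries of a group came from separate plants, so p-values measure the spread between these libraries, which may in part be technical. Libraries of 1 group were compared by a chi-square over tags with 50 or more counts. The value per degree of freedom was 43.2 to 99.6, so no library was a copy of another in its group; pairs across groups were not compared. The labels name no sequencing or library batch.

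Each distinct 20 to 24 nt tag was tested on its raw counts with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM factors, default dispersion estimates and Benjamini-Hochberg adjustment. The library size was the sum of all tags. A tag was kept at 1 CPM (count over the library total, on the usual mega scale) or more in at least as many libraries as the smaller group of the fit held, which was 2 for the 3 spear genotypes and for buds, 3 for Y-bearing against female tips, and 4 for buds against spear tips. A call meant an adjusted p under 0.05. With no difference, a share of about 0.05 of the tests is expected at an unadjusted p under 0.05, and counts at that level are to be read against it. Female, male and supermale tips were fitted together with no other term. A second fit set the 5 Y-bearing tips, male and supermale, against the 3 female ones. Bud fits held sex and stage, which left 1 residual degree of freedom. Buds were compared with the 6 female and male tips with sex in the fit. Fold changes are log2 values from edgeR, and the standard error (SE) was taken from the test statistic.

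Conserved miRNA families were counted from a list of 61 mature sequences in 34 families, written from general knowledge and grouped by the processes their targets serve. A 20 to 22 nt tag joined a family when its first 18 nt differed from a listed sequence by at most 2 bases, and a tag equally near to 2 families was left out. Counts of a family sum over its loci, since members with near-identical sequences cannot be separated without a genome. Families with 10 or more counts over the libraries of a fit were tested with edgeR, using the library sizes and factors of the tag fit. The family named tasiARF is the trans-acting siRNA made from TAS3 transcripts. Adjusted p-values over a list alone were computed beside those over all families.

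Shares of 20, 21, 22, 23 and 24 nt tags were taken over counts of 18 to 26 nt tags and compared by exact two-sided permutation tests, adjusted over the 5 lengths. Fragments of 5.8S and 18S rRNA, plastid 16S rRNA, tRNA-Ala and tRNA-Gly were counted as tags of 18 to 31 nt that lie within a listed sequence, and tested in the same way. Y-limited tags had 10 or more counts in each of 5 Y-bearing tips and 0 in 3 female ones. Single libraries of leaf, root and shoot were given with exact Poisson 95% intervals and a floor of 3 counts. Intervals and floors cover counting error only, since the reads carry no molecular identifiers. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for these steps.

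The line is the replicate label that female, male and supermale tips share, and it was checked as a pairing over 87640 tags. Deviations from the genotype means correlated at 0.446 to 0.760 in all 7 pairs of libraries of 1 line, so the line pairs the samples. A fit with line as a block was run as an alternative. Named families are those past the threshold and the 10 most abundant of the others. Named tags are, per direction, up to 5 past the threshold with the highest mean CPM whose groups do not overlap. These rules, the family list, the designs and the alternatives were set before the data were examined, except where a test is said to have been chosen later. Alternatives were other scalings (relative log expression factors, library size alone, the sum of all families), filters of 0.5 and 5 CPM or none, DESeq2 1.42.0, fewer mismatches, other denominators, and each library left out in turn. DESeq2 took its scaling factors from the counts it tested, which for families are the families alone.

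The tests were run on simulated data, with 200 tags changed by known folds at the observed means and dispersions. Among the 50 tags changed 32-fold, 0% were recovered for male against female and for supermale against male spear tips in the fit without line, 16% for Y-bearing against female tips, 86% for male against female buds, 98% for mid against early buds, and 64% for buds against spear tips. Unchanged tags called in error numbered 0, 1, 53, 190 and 2 in these simulations, of 87640 tested for both of the first, 67461 in the next, 63400 in each bud comparison, and 62973 in the last. The adjusted p-values of tags in buds alone are therefore too small. For miRNA families changed 8-fold, 61.9% were recovered between male and female tips, 78.1% for Y-bearing tips, 73.8% between bud sexes, 57.5% between bud stages, and 86.9% between buds and tips, with at most 0.3 false calls per simulation at any fold. At 2-fold, 9.4% were recovered between buds and tips and 8.75% between bud stages, and 25% and 12.5% of the calls were false. The simulated libraries did not share the spread between lines. The fit with line as a block was not simulated. A genome was not used here, so genome windows and phased loci were left out and tags are given by sequence alone.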

Results

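Garden asparagus is dioecious, and its sex is set by a young Y chromosome. Small RNAs were sequenced from 15 libraries to compare XX, XY and YY plants. Spear tips gave 3 female, 3 male and 2 supermale (YY) libraries from lines 10, 8A and 8B, with no supermale of line 10. Flower buds gave 1 library for each sex at an early and a mid stage, and leaf, root and shoot gave 1 library each. Totals ranged from 44720163 to 53780630 counts in spear tips and from 41237343 to 59076580 in buds. They were 45201020 in leaf, 29122841 in root and 48786670 in shoot.

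In every spear tip and bud library, 24-nt tags were the most abundant length between 20 and 24 nt. This is the class that guides DNA methylation at repeats in plants. In spear tips they made up 49.0% ± 1.58 (SD, n = 3) of 18 to 26 nt counts in females, 49.8% ± 3.08 (n = 3) in males and 50.6% ± 2.67 (n = 5) in Y-bearing tips. Among named families, miR166, which represses HD-ZIP III transcription factors, had the highest counts. It averaged 21125 ± 7076 CPM (n = 8) in spear tips and 23781 ± 5538 CPM (n = 4) in buds. The others with high counts in spear tips were miR159, a repressor of GAMYB factors, at 5085 ± 1089 CPM, miR319, a repressor of TCP factors, at 1312 ± 329 CPM, and miR168, which targets ARGONAUTE1, at 213 ± 46.6 CPM. The level of miR319 may be a lower bound, though without a genome this cannot be told. Tags that match it after 1 extra base at the start were counted under miR159, and may belong to either family. These had 37087 counts beside 90825 of miR319 in the male tip of line 10. In the supermale tip of line 8A they had 54464 beside 59392. Of the 34 families listed, miR444 had 1 count in all libraries together, miR530 had 3, miR529 had 4 and miR162 had 5.

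**Figure D1:**
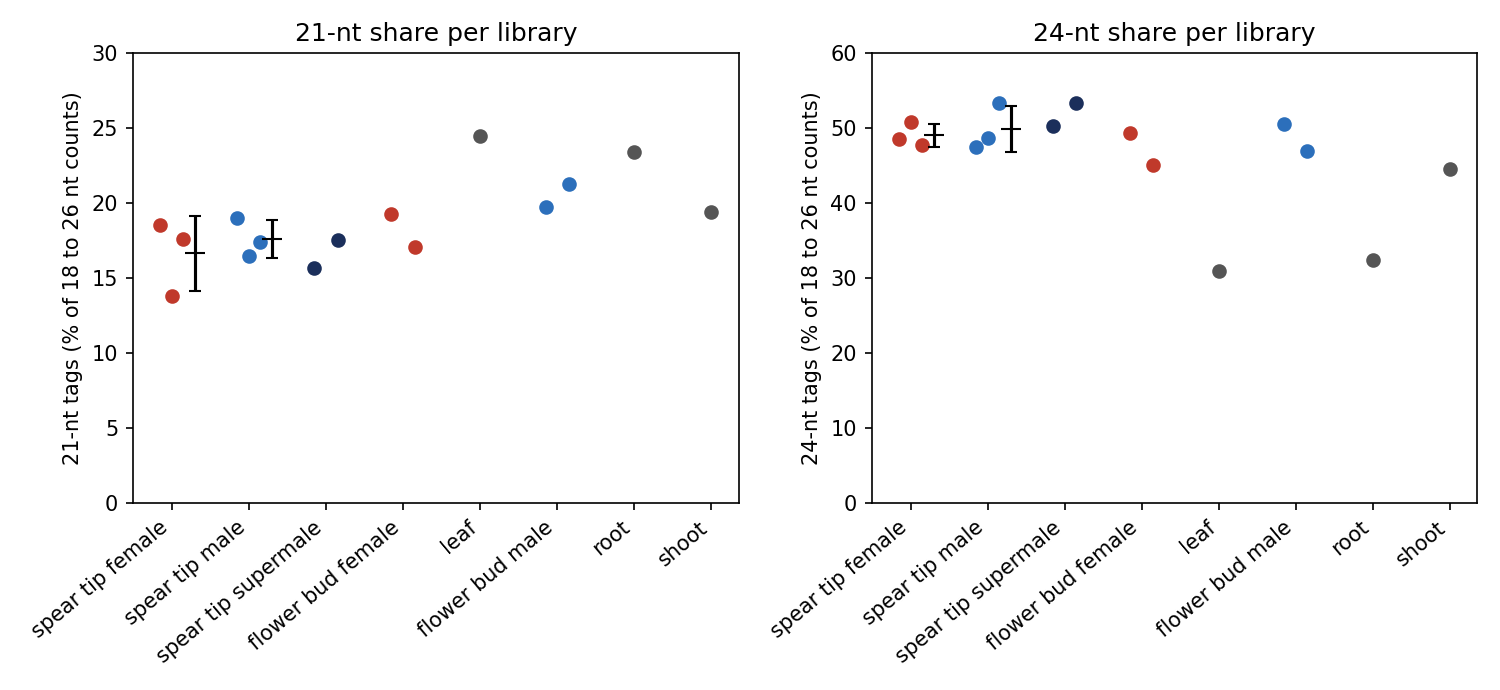
Share of 21-nt and 24-nt tags (% of 18 to 26 nt counts) in each library, by group; points are libraries and, for groups of 3 or more, bars give the mean and SD. The 24-nt share lay at 45.0% to 53.4% in spear tips and buds, against 30.9% in leaf and 32.4% in root.

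Male and female spear tips were compared to ask which small RNAs differ between XY and XX plants before flowers open. The widest difference among measured families with a mean over 1 CPM in either sex was in miR2275, the trigger of 24-nt phased siRNAs in anthers of grasses and other monocots. It stood at 2.92 ± 1.75 CPM (SD, n = 3) in males and 0.315 ± 0.364 CPM (n = 3) in females, and was higher in the male in 3 of 3 lines. miR5179, known to target MADS-box genes of the DEFICIENS type in orchids and grasses, was at 1.15 ± 0.109 CPM in males and 0.514 ± 0.0975 CPM in females, with no overlap. miR396, a repressor of growth-regulating factors, was at 177 ± 23.995 CPM in males and 107 ± 29.6 CPM in females. miR393, which targets auxin receptors, was at 84.6 ± 57.6 CPM in males and 29.9 ± 20.3 CPM in females.

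None of these differences passed the test. In edgeR the log2 fold change of miR2275 was 3.18 (SE 1.27, adjusted p 0.576), that of miR5179 was 1.16 (SE 0.54, adjusted p 0.576) and that of miR396 was 0.72 (SE 0.34, adjusted p 0.576). These values leave line out, though it pairs the tips. Over all alternatives (edgeR or DESeq2), line as a block among them, the lowest adjusted p was 0.0999 for miR2275 and miR5179 and 0.142 for miR396. By edgeR 0 of 27 measured families were called, with 1 at an unadjusted p under 0.05, and DESeq2 called 0. Adjusted over the list alone, 0 families were called in each of the lists for phase change and flowering (3 measured), meristem, leaf and stamen development (6), auxin signalling (5), nutrients, copper and stress (8) and phased siRNA triggers (2). Over the 10 most abundant families, log2 fold changes ran from -0.37 for miR159 to 1.52 for miR393. Of 87640 tags, 0 were called by edgeR, with 2222 at an unadjusted p under 0.05, fewer than a share of 0.05 of the tests. DESeq2 called 335, of which 310 were higher in males. The tag with the smallest p, GATTGATCACGGACCTTAGGTC, was at 3.77 CPM in males and 0.24 CPM in females, and was picked after its values were seen. The fit without line recovered 0% of simulated 32-fold tag changes. With line as a block edgeR called 0 tags and 0 families, with 5988 tags and 7 families at an unadjusted p under 0.05, both more than a share of 0.05 of the tests. The 24-nt share differed by 0.83 percentage points (exact two-sided permutation test, p = 0.8, where 0.1 is the smallest p possible), less than the SD of either sex. It turned to -0.914 points without the male tip of line 8B and to -0.505 points when distinct tags were counted.

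**Figure D2:**
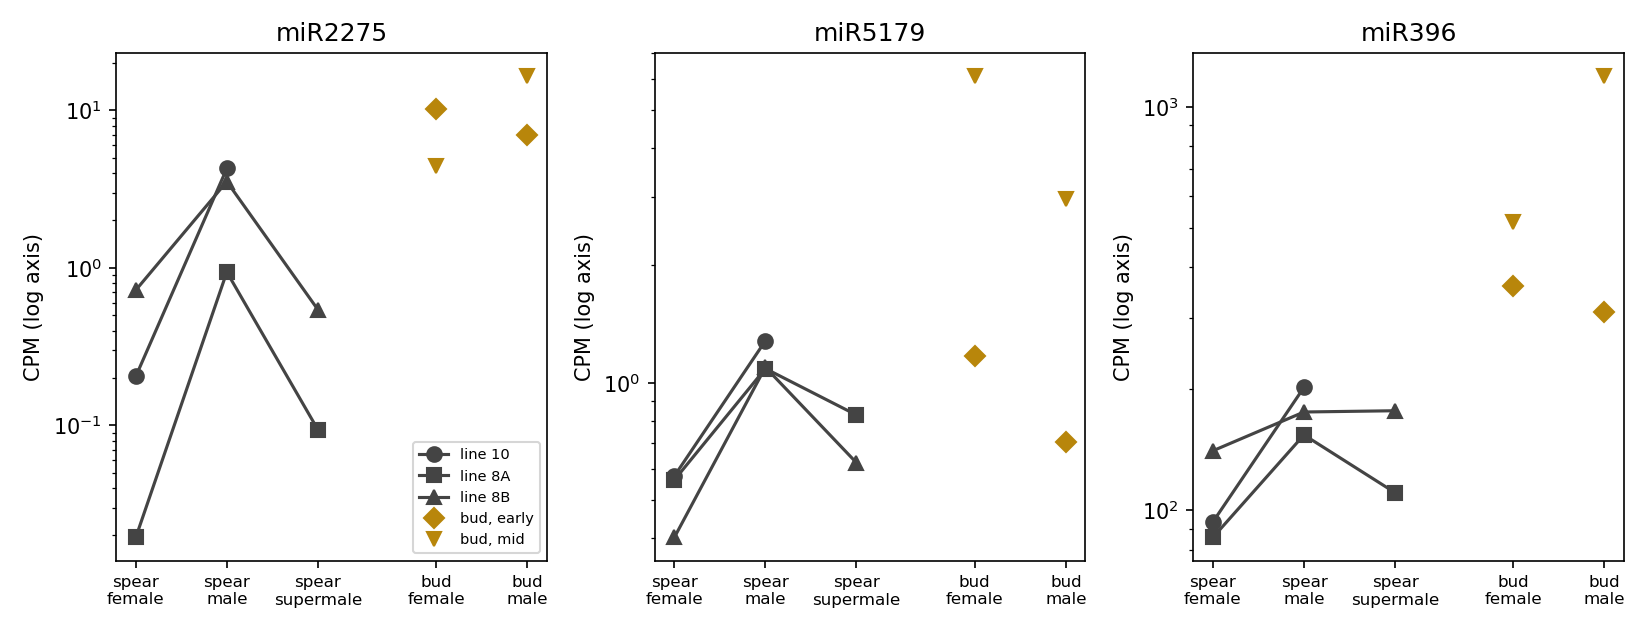
CPM (log axis) of miR2275, miR5179 and miR396 in each spear tip library by genotype, with lines joining libraries of 1 line, and in the 4 flower bud libraries. miR2275 was higher in the male than in the female tip of each line, and reached 4.42 to 16.5 CPM in buds.

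Supermale tips were compared with male and female tips to ask whether a second Y, or the lack of an X, changes small RNAs. In supermale tips miR2275 was at 0.319 ± 0.318 CPM (SD, n = 2), below the male library in 2 of 2 lines and close to the female mean. miR5179 was at 0.725 ± 0.144 CPM and miR396 at 144 ± 46.6 CPM, between the male and female means. None of these families passed the test: the edgeR log2 fold change of miR2275 from male to supermale was -3.07 (SE 1.49, adjusted p 0.916). By edgeR 0 of 27 families were called against males or against females, with 0 at an unadjusted p under 0.05 in either comparison, and DESeq2 called 0. With line as a block 0 were called, with 3 at an unadjusted p under 0.05 against males and 0 against females. The 24-nt tag CGTCCAGAACTCCGCGCAACGAGA had the smallest p in both comparisons, and was picked after its values were seen. It stood at 0.0195 CPM in supermales, 6.03 CPM in males and 7.01 CPM in females, with an edgeR adjusted p of 0.350 against males. Of 87640 tags, 0 were called by edgeR against males and 0 against females, with 1694 and 2217 at an unadjusted p under 0.05, or 4287 and 3712 with line as a block, which also called 0. The fit without line recovered 0% of simulated 32-fold changes from male to supermale. DESeq2 called 427 against males, of which 372 were lower in supermales, and 313 against females, of which 265 were lower.

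Male and supermale tips were then joined to ask what carriers of a Y share. miR2275 averaged 1.88 ± 1.89 CPM (SD, n = 5) in Y-bearing tips and 0.315 ± 0.364 CPM (n = 3) in females, and miR396 averaged 164 ± 34.1 CPM against 107 ± 29.6 CPM. The mean of miR2275 rested on the males, since the supermale tips were at 0.0940 and 0.543 CPM. miR5179 was at 0.624 to 1.28 CPM in Y-bearing tips and 0.401 to 0.576 CPM in females, with no overlap. Neither miR2275 nor miR396 passed the test in edgeR without line, where the log2 fold changes were 2.59 (SE 1.37, adjusted p 0.717) and 0.61 (SE 0.31, adjusted p 0.717). Within lines, miR396 and miR5179 were higher in 5 of 5 Y-bearing tips than in the female tip. For miR2275 this held in all but the supermale tip of line 8B. By edgeR 0 of 27 families were called, with 0 at an unadjusted p under 0.05, and DESeq2 called 0. Of 67461 tags edgeR called 0, with 1851 at an unadjusted p under 0.05, and DESeq2 called 21, all higher in Y-bearing tips. With line as a block edgeR called 0 of each, with 5 families and 3858 tags at an unadjusted p under 0.05. Tags found in each of the 5 Y-bearing tips and absent from the 3 female ones numbered 2, and the mirror set, in 3 female and 0 of 5 Y-bearing tips, numbered 3. One of the 2, TTTTAATGCGACTTGTAAGGT, had 13 to 50 counts in Y-bearing tips, but also 19 and 8 counts in the 2 female buds. The other, AGGACTTGAACAAATGTTGGCT, had 11 to 38 counts in Y-bearing tips, 2 and 21 in the male buds and 1 and 0 in the female buds. The 24-nt share was 1.63 percentage points higher in Y-bearing tips (exact two-sided permutation test, p = 0.375, adjusted p 0.732 over 5 lengths), but by -0.338 points when distinct tags were counted. None of 5 fragment sources passed the test, the lowest adjusted p being 0.387 for 18S rRNA, tRNA-Ala and tRNA-Gly (exact permutation tests). These tests leave line out; tRNA-Ala was lower in 5 of 5 Y-bearing tips than in the female tip of its line, which was not tested.

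Lines stood further apart than genotypes. Across 87640 tags, Pearson's r of log2(CPM + 1) was 0.803 to 0.922 in the 7 pairs of spear tips that share a line. It was 0.563 to 0.724 in the 7 pairs that share a genotype but not a line. Tags are not independent replicates, and these values describe the libraries.

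**Figure D3:**
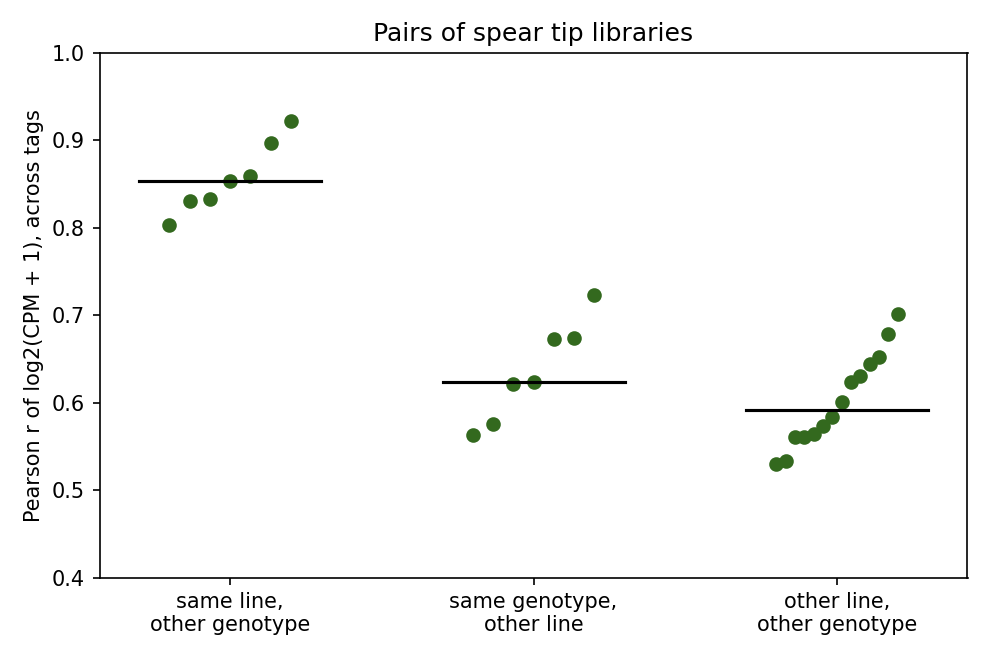
Pearson's r of log2(CPM + 1) across tags for the 28 pairs of spear tip libraries; points are pairs and the bar is the median. The 7 pairs of 1 line all lie above the pairs that share only a genotype, whose highest value was 0.724.

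In flower buds, female and male libraries were compared with stage in the fit, to ask which small RNAs differ between the sexes as flowers form. miR156, a repressor of SPL factors that time flowering, was at 34.7 ± 36.8 CPM (SD, n = 2) in male and 4.84 ± 1.17 CPM (n = 2) in female buds. The male mean rested on the mid male bud at 60.7 CPM, against 8.75 CPM in the early male bud. miR2275 was at 11.7 ± 6.76 CPM in male and 7.28 ± 4.04 CPM in female buds. miR398, which targets copper superoxide dismutases, was at 3.34 ± 1.51 CPM in male and 10.7 ± 7.72 CPM in female buds. By edgeR 0 of 28 families were called, with 2 at an unadjusted p under 0.05. The log2 fold change of miR156 was 2.20 (SE 0.81, adjusted p 0.323 over all families and 0.0346 over its list alone, in edgeR). DESeq2 called 2 families, miR156 higher and miR398 lower in males. Over the other lists, 0 families were called when adjusted over the list alone. Of 63400 tags edgeR called 0, with 6851 at an unadjusted p under 0.05. DESeq2 called 4641, of which 3883 were lower in males. With the filter at 5 CPM edgeR called 664 of 11237 tags, of which 639 were lower in males, and 655 of the 664 were also called by DESeq2 in the same direction, but 132 of them by edgeR without stage in the fit. With 1 residual degree of freedom, 53 unchanged tags of 63400 were called in error in the simulation of this comparison at the filter of 1 CPM. The fit at 5 CPM was not simulated.

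Mid buds differed from early buds in 6 of 28 families by edgeR, 3 lower and 3 higher. miR159, whose GAMYB targets act in anther development, fell by 0.93 on the log2 scale (SE 0.21, adjusted p 0.00447), from 6083 ± 113 CPM (SD, n = 2) to 3097 ± 50.9 CPM. Relative to all families it fell by 0.49, and DESeq2 did not call it, with adjusted p-values of 0.000394 to 0.0816 over its 8 alternatives. miR827, a family of the phosphate response, fell by 1.49 (SE 0.45, adjusted p 0.0188 in edgeR), from 600.2 ± 220 to 199.98 ± 26.4 CPM. miR166 fell by 0.43 (SE 0.12, adjusted p 0.0188 in edgeR), a direction that turned to 0.0099 when counts were taken relative to all families. miR393 rose from 251 ± 199 to 588 ± 88.7 CPM, by 1.54 (SE 0.46, adjusted p 0.0188 in edgeR). miR396 rose from 335 ± 35.4 to 856 ± 476 CPM, by 1.28 (SE 0.41, adjusted p 0.0206 in edgeR). miR5179 rose from 0.939 ± 0.333 to 4.54 ± 2.23 CPM, by 2.28 (SE 0.81, adjusted p 0.0414 in edgeR). Each of the 6 moved the same way in both sexes. Summed rRNA and tRNA fragments also rose with stage, from 3444 to 6536 CPM in female and from 2398 to 3165 CPM in male buds. RNA quality was therefore not separated from stage. By list, 3 of 6 measured families of meristem, leaf and stamen development were called, 1 of 5 of auxin signalling, 1 of 9 of nutrients, copper and stress, and 1 of 1 that targets MADS-box genes. The calls divided differently under other scalings, with 4 higher and 2 lower by library size alone and 8 higher and 2 lower relative to all families. DESeq2 called 3 families, and the fit with no filter called 3. Of 63400 tags edgeR called 0, with 11946 at an unadjusted p under 0.05, and DESeq2 called 7573.

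Flower buds and spear tips were compared to ask how their small RNAs differ, with the sexes balanced. The lines of the bud plants were not given, so tissue cannot be separated from line or plant here. Families that rose in buds came from several lists. miR827 rose from 25.8 ± 17.3 CPM (SD, n = 6) in spear tips to 400.1 ± 264 CPM (n = 4) in buds, miR399, which acts with it in the phosphate response, from 6.12 ± 7.90 to 61.4 ± 30.6 CPM, and miR393 from 57.3 ± 48.9 to 419.7 ± 232 CPM. The phased siRNA trigger miR2275 rose from 1.62 ± 1.82 to 9.51 ± 5.23 CPM, and miR396 from 142 ± 45.5 to 595 ± 408 CPM. Smaller rises were seen in miR164, which targets NAC factors of organ boundaries, from 1.35 ± 0.665 to 3.86 ± 0.573 CPM, in miR167, which targets auxin response factors, from 66.0 ± 31.8 to 171 ± 112 CPM, and in miR171, which targets HAIRY MERISTEM factors, from 19.7 ± 7.05 to 37.4 ± 3.03 CPM. Most of these levels were not particular to buds. The single leaf library held 411 CPM of miR827, 158 CPM of miR399, 566 CPM of miR393 and 2502 CPM of miR396. It also held 687 CPM of miR167, 9.05 CPM of miR164 and 45.5 CPM of miR171, each of these families being above its bud mean. In contrast, miR2275 was at 0.111 CPM in leaf. Its highest spear tip, the male of line 10, had 4.28 CPM, beside 4.42 CPM in its lowest bud, the mid female.

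By edgeR 9 of 28 families were called, all higher in buds. This fit took the 6 tips as independent, though line pairs them, so its SEs and p-values may be too small. Log2 fold changes were 3.90 for miR827 (SE 0.64, adjusted p 0.0022), 3.47 for miR399 (SE 0.86, adjusted p 0.0151), 3.40 for miR2275 (SE 0.91, adjusted p 0.0188) and 3.13 for miR393 (SE 0.73, adjusted p 0.0136). They were 2.12 for miR396 (SE 0.37, adjusted p 0.0022), 1.57 for miR164 (SE 0.45, adjusted p 0.0188), 1.47 for miR167 (SE 0.41, adjusted p 0.0188) and 1.01 for miR171 (SE 0.32, adjusted p 0.0310) in edgeR, though 0.09 for miR171 when no mismatch was allowed. The ninth, miR408, was near the floor, with 1 count in 6 spear tips and 0, 8, 4 and 7 counts in the buds. By list, 3 of 6 families of meristem, leaf and stamen development rose, 2 of 5 of auxin signalling, 3 of 9 of nutrients, copper and stress, 1 of 2 phased siRNA triggers and 0 of 3 of phase change and flowering. miR166, miR159, miR319 and miR168 were not called, with log2 fold changes of 0.19, -0.17, -0.25 and -0.08. miR5179 was at 2.74 ± 2.45 CPM in buds and 0.834 ± 0.363 CPM in spear tips, and was not called over all families (adjusted p 0.0676 in edgeR). Its list held 1 measured family, so its p over the list alone, 0.0241 in edgeR, is unadjusted. miR396 passed in all 18 alternatives and miR827 in all 17 that gave a value. Without the mid male bud these 2 families were called, without the mid female bud 5, and without the male spear tip of line 8A 5. DESeq2 called 5, with miR393, miR396 and miR2275 higher and miR319 and miR390 lower in buds. Its scale came from the families alone, whose median log2 fold change in edgeR was 0.79. Its lower calls are therefore relative to the other families.

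**Figure D4:**
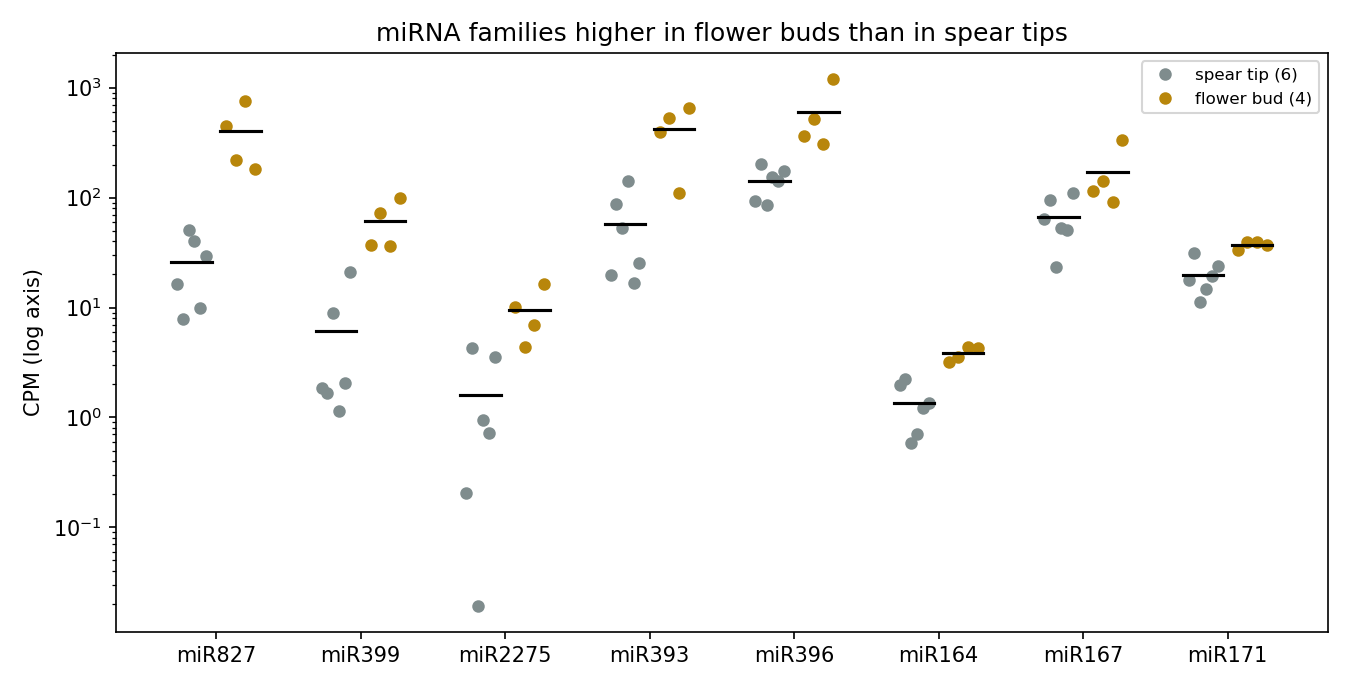
CPM (log axis) of the 8 miRNA families that edgeR called higher in flower buds (4 libraries) than in female and male spear tips (6 libraries), leaving out miR408; points are libraries and bars are means. miR827 averaged 400.1 CPM in buds and 25.8 CPM in spear tips.

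Of 62973 tags, 7135 were called by edgeR between buds and spear tips, 3884 higher and 3251 lower in buds. As for families, the fit left out the pairing of tips by line, so p-values of tags may be too small. Tags of 21 nt, the usual length of miRNAs, were 28.8% of those higher, 11.8% of those lower and 17.3% of those not called. The named tags higher in buds were AGTTACTAATTCATGATCTGGC at 4021 ± 1058 CPM (SD, n = 4) against 1260 ± 328 CPM (n = 6), TTATGAGATTGAGGATATACT at 2699 ± 1252 against 1061 ± 217 CPM, and TAACGAAATGGATTATCGGTCC at 1535 ± 372 against 693 ± 114 CPM. The 24-nt tag AGAGAAGATTGCCACTAGAACAAG was at 1234 ± 1459 CPM in buds and 78.7 ± 35.7 CPM in spear tips, with a log2 fold change of 3.82 (SE 0.60, adjusted p 0.00534 in edgeR) and its highest value, 3399 CPM, in the mid male bud. TAAAACCGGGCCTGGACTTAG was at 862 ± 235 against 268 ± 139 CPM, with an edgeR adjusted p of 0.0481. Tags lower in buds were GACTTAATGATTATTCGTTC at 168 ± 40.3 against 409.8 ± 71.2 CPM, TCAAGGGACTTGTTTTTGCTCT at 167 ± 47.3 against 361 ± 50.3 CPM, and ATAGTGACTGCATTGATAGACATT at 59.2 ± 17.3 against 119 ± 10.9 CPM. The overlapping tags ATTGGACGGAATTCTGACTAC and CATTGGACGGAATTCTGACTA were at 105 ± 18.8 against 313 ± 83.8 CPM and 86.7 ± 14.4 against 237 ± 49.6 CPM. None of these 10 tags matched a listed family. Without the mid male bud 509 tags were called, without the early female bud 1152, without the mid female bud 1542, without the female spear tip of line 8B 4435 and without the early male bud 4449.

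The size classes of buds and spear tips did not differ past the threshold. The 24-nt share was 47.9% ± 2.43 (SD, n = 4) in buds and 49.4% ± 2.23 (n = 6) in tips, and the 21-nt share 19.3% ± 1.74 against 17.1% ± 1.84 (exact two-sided permutation tests, p = 0.352 and 0.0905, adjusted p 0.587 and 0.452). Over all tags the difference in the 24-nt share turned from -1.50 to 0.744 points. Fragments of 18S rRNA were at 716 ± 248 CPM in buds and 1224 ± 274 CPM in tips (exact two-sided permutation test, p = 0.0190, adjusted p 0.0952 over 5 sources). The test of whether the male to female difference itself differed between buds and tips called 0 of 28 families in edgeR, with 0 at an unadjusted p under 0.05; it was not run in DESeq2. Its largest terms with mean levels above 1 CPM in buds were for miR528 at -4.51 (SE 2.50), miR2275 at -2.62 (SE 1.55) and miR5179 at -2.37 (SE 1.27), each with an adjusted p of 0.944.

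Leaf, root and shoot, with 1 library each, show tissue profiles without a replicate check. Leaf held 47034 CPM of miR166 (exact Poisson 95% interval 46971 to 47097), 2502 CPM of miR396 (2487 to 2517), 687 CPM of miR167 (679 to 695) and 306 CPM of miR398 (301 to 311). Root held 141 CPM of miR156 (137 to 145) and 123 CPM of miR535 (119 to 127), but 0.687 CPM of tasiARF (0.419 to 1.06), 0.584 CPM of miR390, which starts tasiARF production (0.340 to 0.935), and 0.446 CPM of miR171 (0.238 to 0.763). Shoot held 9612 CPM of miR159 (9584 to 9639) and 3294 CPM of miR319 (3278 to 3310). That level of miR319, 160709 counts, leaves out 136669 counts of tags that match it after 1 extra base at the start. Those tags were counted under miR159 and may belong to either family. miR2275 had 5 counts in leaf, 1 in root and 0 in shoot, where the floor of 3 counts is 0.0615 CPM. The 24-nt share was 30.9% in leaf (Wilson 95% interval 30.92% to 30.95%), 32.4% in root (32.39% to 32.43%) and 44.5% in shoot (44.51% to 44.54%).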

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

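Tests chosen after the result was seen were the count of Y-limited tags over other splits, the tests of chance counts of 0 and of too few reads in line-limited tags by other groups of libraries, the test of differences between lines, and the ratio of male to female amounts in tags absent from supermales.

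Single libraries far from the others of their group were looked for in 81 groups of values, and 8 were found, where chance gives about 1 in 20 groups. miR399 reached 21.1 CPM in the male spear tip of line 8B, where the nearest of the 5 Y-bearing tips had 3.53 CPM. miR408 stood at 0.0209 CPM, a single count, in the male tip of line 8A, far from the others both among the Y-bearing tips and among the 6 female and male tips, all at 0. miR319 reached 1736 CPM in the male tip of line 10, with 1197 CPM in the nearest Y-bearing tip, but the female tip of line 10, left out of that group, had 1896 CPM. Fragments of plastid 16S rRNA reached 399.7 CPM in the female tip of line 8B, against 215 CPM in the nearest library. Fragments of tRNA-Gly reached 391 CPM in the male tip of line 8A, against 179 CPM in the nearest of the 6 female and male tips, but the supermale tips, left out of that group, had 423 and 428 CPM. In buds, the mid male library stood apart for miR156, at 60.7 CPM against 8.75 CPM, and for miR168, at 312 CPM against 177 CPM. Tags of 25 to 46 nt, outside the size classes tested, took from 6.48% of all counts in the mid male bud to 36.7% in root.

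Whole sets of small RNAs were found in 1 line of spear tips alone. Tags with 10 or more counts in every library of a line and 0 in all other spear tips numbered 16072 for line 10, 3947 for line 8A and 2867 for line 8B. Line 10 had 2 libraries and the other lines 3 each, so its rule was easier to meet and the counts do not rank the lines. A chance count of 0 in rare tags of like level in all lines is argued against. Splits with 1 library of each line gave at most 8 tags present in 5 libraries and absent from 3 and at most 5 of the mirror kind. Tags limited to 2 libraries of different lines numbered at most 100. Too few reads cannot be decided by these counts, since a tag lower in the other lines and missed there would follow the line too. The median lowest count, scaled to the smallest library, was 14.97, just on the side of 15 set before this value was computed as the mark of too few reads; that mark was badly set, since tags enter at 10 counts and that minimum alone may hold the median near it. Sequence variants between lines may account for a part of unknown size. A partner 1 base apart, present in both other lines and absent from that line, was found for 2.31% of these tags (exact 95% interval 2.12% to 2.51%). Among control tags found in all 8 libraries the share was 0.219%. Partners needed the same length, 1 substituted base and 10 or more counts in every library of the other lines, so other variants were missed. Differences in expression between plants of the lines stay open, untested.

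A set of tags was lower in male than in female flower buds, though the filter of 1 CPM gave 0 calls in edgeR, with 6851 tags at an unadjusted p under 0.05 and 4641 called by DESeq2. With the filter at 5 CPM, 639 tags were lower in male buds, with medians of 14.4 and 18.4 CPM in the early and mid female buds and 1.48 and 2.54 CPM in the male ones. Of the 586 tested in spear tips, 9.39% differed between lines (exact 95% interval 7.15% to 12.0%) against 14.9% of all tested tags. The set was thus not enriched for tags that differ between the lines of spear tips. Differences between the bud plants are not decided by this, since their lines were not given and tag lengths were not matched. A difference between the sexes in every tissue is argued against for most of these tags. Only 15.2% were higher in the female tip in all 3 lines (exact 95% interval 12.4% to 18.4%), close to the 14.7% of all tested tags. But these were 89 tags, while 33 were higher in the female tip in 0 lines. That last share was not computed for all tested tags, so such a difference in a part of the set stays open. A bud-specific difference between the sexes, a difference between the plants that gave these 4 libraries and RNA quality stay open, untested, because each sex and stage has 1 library: rRNA and tRNA fragments were at 3444 and 6536 CPM in the early and mid female buds against 2398 and 3165 CPM in the male ones, and 22.4% of the 639 tags were 24 nt long, against 47.0% of all tested tags.

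Tags missing from YY plants were looked for after the smallest p-values against supermales fell on such tags. In 138 tags both supermale tips had 0 counts and each of the other 6 tips had 10 or more, while the highest of the other 8 pairs of 1 library of line 8A and 1 of line 8B gave 75, and pairs of line 10 with another line gave up to 103. Sequence that YY plants lack, such as sequence on the X alone, may explain the excess, but a chance count of 0 in rare tags stays open, because 75 is more than 50 percent of 138 and 103 lies nearer still. The median male to female ratio, 0.872 in the lowest line and 1.40 in the highest, does not decide whether amounts follow the number of X copies, since the tags were required in every male tip and chance zeros may fill much of the set. Of these tags 88.4% were 24 nt long, and they fell into 107 groups that share 16 bases. One of them, ATTGGAGAACAAGAACTAAACATT, averaged 4.297 CPM in the 6 tips and was at 0 in both supermale tips.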

How the results depend on the processing

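The reassignment to miR319 of tags that match it after 1 extra base was chosen after seeing the data, and it changed no count of called families. Counts of called families between spear genotypes stayed at 0 under all 16 alternatives each, and the sex by tissue test at 0 under 3. DESeq2 called 335 tags between male and female tips, 427 and 313 for supermale against male and female tips, 21 for Y-bearing tips, 4641 for bud sex, 7573 for bud stage and 16892 for buds against tips, and 2, 3 and 5 families in the 3 bud comparisons. Why DESeq2 called more tags was not tested, and for these and the following changes the cause was not tested unless given. At a filter of 5 CPM, 664 tags were called for bud sex and 1571 for buds against tips, where fewer tags were tested, and at 0.5 CPM 13097 for the latter. Without stage in the fit, bud sex gave 436 tags and 1 family, and with no filter on families 1 for bud sex and 3 for bud stage. Relative to all families, 10 were called for bud stage, the median log2 fold change of all families moved from 0.28 to 0.71, and miR166 turned from a fall to 0.0099. The same scaling moved that median by -0.22 for bud sex, -0.14 for Y-bearing tips and -0.13 for buds against tips, and library size alone moved it by 0.18 in the sex by tissue test. The 24-nt share turned to -0.505 for male and -0.338 for Y-bearing against female tips when distinct tags were counted, and to 0.744 for buds against tips over all tags. Leaving out 1 library gave -0.914 (without the male tip of 8B) to 1.99 for the 24-nt share of males. For buds against tips it gave 509 to 6062 tags: 509 without the mid male bud, 1152 without the early female, 1542 without the mid female, 4449 without the early male bud and 4435 without the female tip of 8B. Families gave 2 to 10: 2 without the mid male bud, 5 without the mid female bud and 5 without the male tip of 8A. Y-limited tags numbered 10 at a minimum of 5 counts and 0 at 20, as the definition was widened or narrowed. Families that edgeR called and the 10 named tags kept their direction under every alternative that gave a value, miR166 in bud stage excepted. miR390, not called, turned from 0.00 to -0.76 between buds and tips with DESeq2, which called it on a scale taken from the families alone. Between buds and tips miR396 and miR827 also stayed past the threshold throughout, while miR171 passed in 9 of 18 alternatives and TAAAACCGGGCCTGGACTTAG in 7 of 16. miR156 passed for bud sex with DESeq2 and without stage in the fit. The line as a block changed no call in spear tips, but raised the tags at an unadjusted p under 0.05 between male and female tips from 2222 to 5988. Bud libraries could not be left out within buds, with no residual degrees of freedom left, and the genome windows and phased loci were not run, since no genome was among the files used here. In simulation the fit without line recovered 0% of 32-fold tag changes between male and female tips. Whether depth, the number of libraries or the spread between lines limits that count was not tested.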

Other observations

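Small RNAs from repeats and from young miRNA genes often differ between plant lines. The labels do not say how lines 10, 8A and 8B are related. Tests of differences between lines and of reassigned miR319 tags were chosen after the data were seen. In a fit with line and genotype, edgeR found 13050 of 87640 tags (14.9%) different between lines and 0 between genotypes, with 5008 at an unadjusted p under 0.05 for genotype; DESeq2 was not run on that fit. The share was 21.6% among 21-nt tags and 21.5% among 22-nt tags, against 12.54% among 24-nt tags. The 22-nt tag TAGAATCCAACATCGTCGATTT had 688 and 946 CPM in the tips of line 10 and at most 0.503 CPM elsewhere. TTCATGGACGTTGATAAGATCCT had 9749 to 30576 CPM in line 8A and 1247 to 3583 CPM in the other lines. TCACCCATCTTCTCGTGACGAG had 204 to 257 CPM in line 8B, 43.1 and 57.6 CPM in line 10 and at most 0.117 CPM in line 8A.

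Conserved families differed between lines too, 8 of 27 by edgeR. miR166 averaged 27384 ± 656 CPM (SD, n = 2) in line 10, 12888 ± 3044 CPM (n = 3) in line 8A and 25189 ± 231 CPM (n = 3) in line 8B, with an edgeR adjusted p of 0.0187. tasiARF averaged 66.1, 37.0 and 71.1 CPM in lines 10, 8A and 8B, miR160 61.3, 21.8 and 37.7 CPM, and miR168 209.9, 260.4 and 167 CPM. miR156 averaged 3.06, 5.13 and 14.3 CPM (adjusted p 0.0477 in edgeR). The others were miR164, miR167 and miR393. Tags that match miR319 after 1 extra base at the start made up 6.32% to 29.1% of the counts of miR159.

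Other splits of the libraries were set beside the real comparisons. For buds against spear tips chance can be excluded only if the 6 tips count as independent, whereas they are 3 pairs by line: 7135 tags were called against at most 1413 in the other splits, of 100 drawn with a fixed seed, and 9 families against at most 3, with the real split alone (1 of 100) as large. These splits do not separate tissue from the unlabelled lines of the bud plants, and miR164, miR167 and miR393, higher in buds, also differed between lines of spear tips. The split with 1413 put tips of lines 8A and 8B against the rest, and splits that keep lines whole were not counted on their own. For Y-bearing against female tips 0 tags and 0 families were called against at most 4242 and 3; with 0 in the real split all 56 splits give as many by construction, so nothing follows about chance. The split with 4242 set lines 10 and 8B against line 8A, which points to the lines as a structure of these libraries. For Y-limited tags chance cannot be excluded either, with 2 against at most 3161, and 43 of 56 splits gave as many. Among the 18 splits with 1 library of each line, which part the lines as the real one does, the highest other gave 8. Male and female tips make 10 splits, too few for a share under 0.05, with 0 tags against at most 1 and 0 families against at most 0.

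In buds, 3 tags of the smallest p between the sexes were picked after their values were seen. CGGATTCTACCTTTACTCGGGC stood at 54.1 CPM in female and 0.0540 CPM in male buds, TTTGTGCAGCCATCCACCAAGGAA at 93.1 and 0.0750 CPM, and TCTCGATGGATGGCTGCACAAAGC at 47.4 and 0.0298 CPM, each with an edgeR adjusted p of 0.0602.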
